A study of Mus musculus with 8 samples.

How the data were processed

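The study measured RNA from the epithelium of the lower molar tooth germs of mouse embryos at embryonic day E13.5 on 8 Affymetrix expression arrays. Foxi3 encodes a forkhead transcription factor of the dental epithelium, and the conditional knockout (cKO) deletes a floxed Foxi3 allele with a Cre recombinase under a keratin 14 promoter (K14-cre43), which is active in epithelium. Per the labels' protocols, the epithelium was separated from the underlying tissue with dispase, the molars of 5 embryos of 1 genotype were pooled for each sample, and the RNA was labelled with the WT Terminal Labeling Kit. The 8 samples fell into 2 groups of 4 pools by the genotype in their titles. The controls are titled wild type, while their genotype label reads Foxi3+/floxed. The cKO label names the Cre and the floxed allele, and the series' design text adds that the other Foxi3 allele was a null allele. As printed, the control label names neither a Cre nor a null allele. Effects of the Cre, the null allele and the epithelial deletion therefore cannot be told apart here.

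The authors deposited 1 table of log2 expression values, made with RMA per the submitters' processing notes. The version of RMA, the array model and the genome build were not given in the sources used here. RMA corrects the background, sets the probe distributions of all arrays equal and summarises the probes of a gene, and it narrows large fold changes and those of dim genes. The table had 26165 rows, each with a unique Ensembl mouse gene identifier, and its values ran from 1.13 to 12.6. Its 8 columns carry the sample accessions and were matched by them, and no column was left unused. No 2 arrays held identical values. The table gave no detection call and no signal over background, so no gene was called absent. For arrays, the number of pools limits the precision.

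The deposited table does not pair the identifiers with gene symbols, and none of the 26165 identifiers could be matched in the gene table used here, whose Ensembl column was empty. Genes are therefore given by their identifier. The value of Foxi3 itself, the genes next to it on the chromosome and the 24 gene lists fixed before the data were examined (tooth signalling centres, signalling pathways, keratinocyte differentiation, markers of mesenchyme, blood and other cell types, handling stress and sex) were not analysed here, so neither the deletion nor the cell makeup of the pools was checked. The naming rule, also fixed beforehand, took the genes with the largest rise and the largest fall among those past the threshold. With identifiers only it was limited to 2 genes in each direction, and its exclusion of genes with systematic names could not be applied. Each gene had 1 row, so the planned rule for genes with several probe sets, and its alternative, changed nothing, and the planned test of all rows is the main test.

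The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), with genotype as the only term, on the deposited log2 values without further normalization or filter. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 26165 genes, and a gene was called at an adjusted p under 0.05. Differences are log2 values of cKO minus wild type, with the moderated standard error (SE). The p-values measure the spread between these pools.

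In place of the symbol-based lists, 3 lists of cell cycle genes were added after the table had been seen and before they were tested. They came from the mouse marker pairs distributed with the scran R package, which name Ensembl identifiers. A gene entered the list of a phase (G1, S or G2M) if it was in at least 10 pairs of that phase and was the higher member in at least 80% of them, and a gene that met this for more than 1 phase was left out. Lists were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry, each adjusted over the 3 lists.

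The limma step was tested on simulated data: 5 sets of 8 arrays with the real means and spreads of the 26165 genes, in which 200 genes were changed. In this simulated comparison of cKO with wild type, 64.6% of the genes changed by 0.5 and 91.2% of those changed by 1 on the log2 scale were called with the right sign, and 5.58% of all calls were false. With no gene changed, no gene was called in any of the 5 sets. The simulated values were drawn independently for each gene and array, with no correlation between genes and no deviant array. These rates therefore need not hold for the real arrays.

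Samples with the same replicate number in both genotypes did not deviate together: the correlations of their deviations from the group means were −0.046, −0.090, −0.037 and 0.020 for numbers 1 to 4. The labels do not say that a number marks a shared litter or day, so the numbers were not treated as pairs. Alternatives tried were the replicate number as a block, leaving out each array, repeated quantile normalization, centring each array on its median, a filter on dim genes, a variance prior with trend and robust fitting, array weights, a gene-by-gene test without shared variance, and other limits on adjusted p and fold change. Cyclic loess normalization and leaving out both arrays of lowest weight were added after seeing the data. The labels gave no date or batch, so none was tested.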

Results

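Gene expression was profiled in molar epithelium of 4 Foxi3 cKO pools and 4 wild-type pools, each from 5 E13.5 embryos. The aim was to find genes expressed differently between these genotypes in the early tooth germ. By the labels and design text the genotypes also differ in the Cre and a null allele, so differences cannot be assigned to the epithelial deletion alone. Values were log2 RMA expression for 26165 genes. Median expression was between 5.25 and 5.30 on 7 of the arrays and 5.44 on wild-type replicate 2. Correlations between arrays, across genes, ranged from 0.989 to 0.996.

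In the cKO epithelium 342 of the 26165 genes (1.31%) were called different from wild type, 180 of them higher and 162 lower (limma, adjusted p under 0.05). Genes not called were not shown to be unchanged, and the count moved with the setting, as given below. Among the called genes, the largest rise was that of ENSMUSG00000031073, 5.50-fold higher in the cKO. The largest measured fall was that of ENSMUSG00000000560, 3.90-fold lower, with a dim cKO signal. Most differences were small. The median size among the called genes was 0.43 on the log2 scale, a 1.35-fold difference, and 209 of the 342 differed by less than 0.5. At least a 2-fold difference was reached by 18 genes, of which 6 were higher and 12 lower in the cKO. Every called gene had 4 cKO values on one side of all 4 wild-type values, which the threshold makes likely in itself. Such separation was seen in 7.85% of all genes, against 2.86% expected by chance with 4 arrays in each group.

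ENSMUSG00000031073 had an expression of 8.24 ± 0.22 (SD, n = 4) in the cKO and 5.78 ± 0.13 (SD, n = 4) in wild type. The difference was 2.46 (SE 0.11, limma adjusted p = 0.000315), and this gene also had the smallest p of all genes. The next largest rise among the called genes was that of ENSMUSG00000062760, from 6.16 ± 0.11 (SD, n = 4) in wild type to 7.38 ± 0.16 (SD, n = 4) in the cKO. This was a difference of 1.22 (SE 0.09, limma adjusted p = 0.00109), or 2.33-fold. ENSMUSG00000000560 fell from 6.47 ± 0.30 (SD, n = 4) in wild type to 4.50 ± 0.13 (SD, n = 4) in the cKO, a difference of −1.96 (SE 0.15, limma adjusted p = 0.00109). Its lowest wild-type value, 6.02 in replicate 2, was still above its highest cKO value of 4.69. ENSMUSG00000054005 fell from 5.99 ± 0.17 (SD, n = 4) to 4.51 ± 0.26 (SD, n = 4), a difference of −1.48 (SE 0.13, limma adjusted p = 0.00279), or 2.79-fold. With the replicate number as a block, its limma adjusted p was 0.059. The cKO signals of these 2 genes were dim and could not be told from background, so their falls of 3.90-fold and 2.79-fold may be lower bounds and their order is uncertain.

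**Figure D1:**
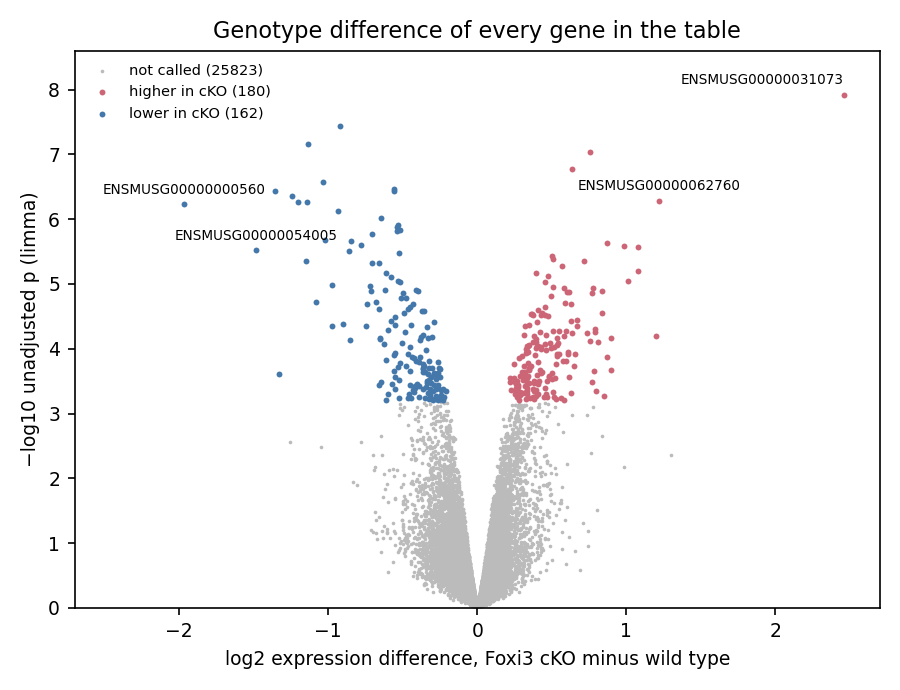
Each point is 1 of 26165 genes, with the log2 expression difference between Foxi3 cKO and wild type on the horizontal axis and −log10 of limma's unadjusted p on the vertical axis. The 180 genes called higher in the cKO are red and the 162 called lower are blue. ENSMUSG00000031073 lies farthest to the right, at 2.46.

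**Figure D2:**
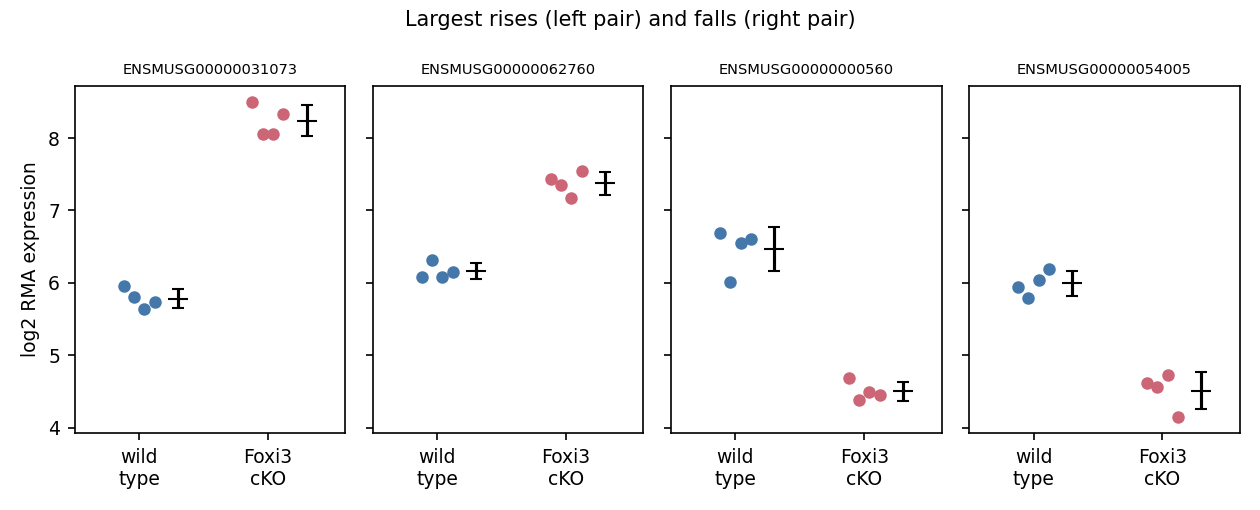
Log2 RMA expression of the 2 genes with the largest rise and the 2 with the largest fall among the called genes. There is 1 point per pool (4 wild type in blue, 4 Foxi3 cKO in red), and the mean with its SD is in black. In each gene the cKO and wild-type values do not overlap, and ENSMUSG00000031073 averages 8.24 in the cKO against 5.78 in wild type.

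Most called genes gave bright signals, which for different probes do not rank expression levels. By mean signal over all arrays, 194 were in the brightest tertile of the genes, 133 in the middle tertile and 15 in the dimmest tertile. Genes that crossed into or out of the dim range, set at the 40th percentile of mean signal (4.72), were few in both directions. Of the genes higher in the cKO, 12 were below that level in wild type and above it in the cKO, while 162 were above it in both genotypes. Of the genes lower in the cKO, 16 went below it in the cKO, among them ENSMUSG00000000560 and ENSMUSG00000054005, and 134 were above it in both. ENSMUSG00000031073 and ENSMUSG00000062760 were above that level in both genotypes.

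The share of called genes that were higher in the cKO, 52.6%, became 66.8% of 196 genes when each array was centred on its median. Centring takes most from wild-type replicate 2, whose median was 5.44 against 5.25 to 5.30 on the other arrays. It thereby raises cKO minus wild type for every gene, so the larger share is no separate evidence of direction. The median difference over all genes was −0.018 as deposited. The 342 calls became 575 with array weights and 18 with the replicate number, not stated to mark pairs, as a block. They became 128, 121, 138 and 119 without cKO replicates 1, 2, 3 and 4, and 201, 185 and 141 without wild-type replicates 1, 3 and 4. Without wild-type replicate 2, the array that stood apart, 303 genes were called, 256 of them among the 342, and 16 genes differed at least 2-fold. Without both arrays of lowest weight, wild-type replicate 2 and cKO replicate 1, 106 genes were called.

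Genes tied to cell cycle phases showed very small differences as groups. Of 118 measured genes of the G2M list (genes highest late in the cycle and in mitosis), 88 had a positive and 30 a negative difference, but 2 were called higher and none lower, and the mean difference was 0.058 on the log2 scale. Adjusted over the list alone, the same counts of 2 and 0 were obtained. With limma's camera at the preset correlation the list stood above the other genes (adjusted p = 5.3e-07), and with an estimated correlation it did not (adjusted p = 0.46). The 113 measured genes of the S list averaged 0.034, with 1 gene called lower and none after adjustment over the list alone. The camera adjusted p was 0.000275, and 0.46 with an estimated correlation. The 158 measured genes of the G1 list averaged 0.025, with 2 genes called lower, and 2 when adjusted over the list alone. The camera adjusted p was 0.00307, and 0.46 with an estimated correlation.

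Wild-type replicate 2 had the lowest average of the G2M list. Relative to the mean of all arrays, its G2M genes averaged −0.12, against −0.024 to 0.013 in the other wild-type arrays and −0.0041 to 0.045 in the cKO arrays. Its median deviation from the other wild-type arrays was −0.063 in the brightest tertile of genes and 0.160 in the dimmest. Such a trend can lift a list of bright genes in cKO minus wild type. The S mean was 0.034 with and without the dimmest 40% of genes. After cyclic loess, which removes dependence on brightness, the G2M list was still called (camera adjusted p = 0.000934). The S and G1 lists were not (camera adjusted p = 0.053 and 0.15). Without wild-type replicate 2 the G2M list averaged 0.029 (camera adjusted p = 0.071), the S list 0.0065 and the G1 list −0.0047 (adjusted p = 0.60 for both). Without both it and cKO replicate 1 the G2M list averaged 0.040 and was called at the preset correlation (camera adjusted p = 0.000537), and with array weights it averaged 0.043 (adjusted p = 0.000157). Centring each array on its median raised the means to 0.093 for G2M, 0.068 for S and 0.060 for G1, all called at the preset correlation. This adds the same amount to every gene, moving the median over all genes from −0.018 to 0.017, and leaves the mean distance of a list from the other genes unchanged. An estimated correlation was run on the deposited values only, where it left none of the 3 lists called (camera adjusted p = 0.46 each). The called share was 1.69% in the G2M list and 1.31% among all genes, with p = 0.67 by Fisher's exact test (two-sided, one of 3 such tests, the other 2 with p = 1).

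Over all genes, the first principal component, with 34.4% of the variance, set wild-type replicate 2 apart at a score of 38.1, while the other 7 arrays lay between −10.9 and 0.84. The second component, with 17.5%, held cKO replicate 1 at −21.7 and the other cKO arrays between −5.34 and −2.08. On that component the wild-type arrays lay between −0.42 and 13.4. The median SD per gene was 0.078 among cKO arrays, 0.115 among wild-type arrays, and 0.070 among wild-type arrays without replicate 2. Each array was also placed on an axis from wild type (0) to cKO (1), over genes called without that array. The cKO arrays lay between 0.92 and 1.02 and the wild-type arrays between −0.054 and 0.12.

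**Figure D3:**
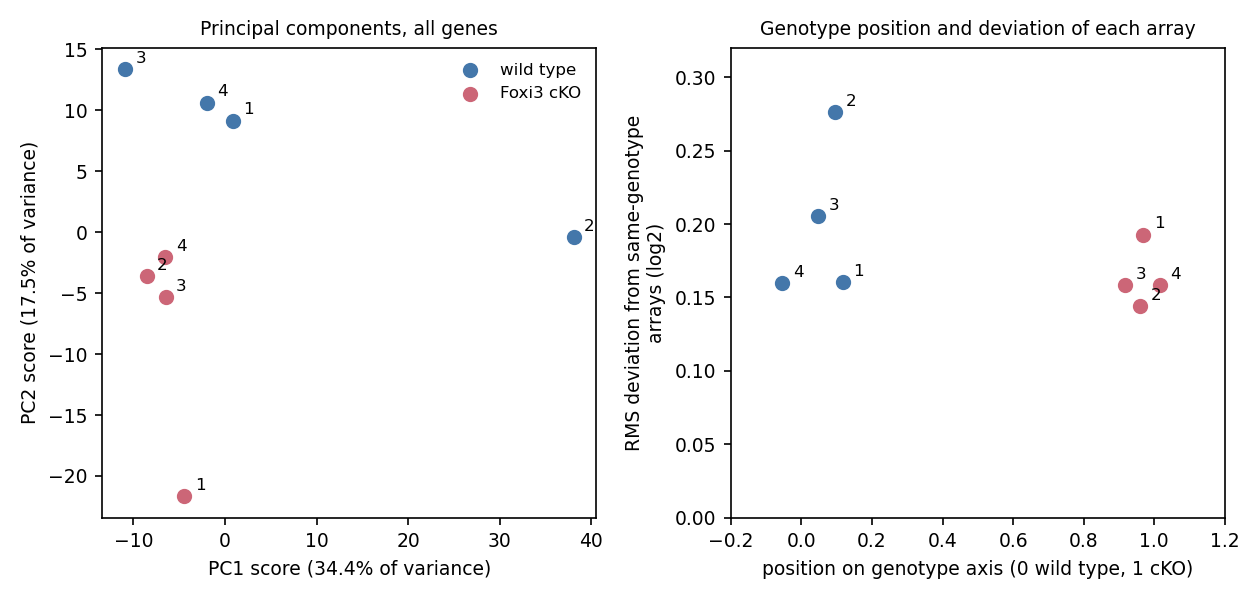
Left, scores of the 8 arrays on the first 2 principal components of all genes (34.4% and 17.5% of the variance). Right, the position of each array from wild type (0) to cKO (1), over genes called without it, against its root mean square deviation in log2 units from the mean of the other arrays of its genotype. Numbers are replicates, wild type is blue and Foxi3 cKO red. Wild-type replicate 2 deviates most (0.276) and lies at 0.096 on the genotype axis.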

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

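The test of a brightness trend below was chosen after the array had been seen to stand apart, and the cell cycle lists were added after the table had been seen. Each measure was checked in each group of 4 arrays for a highest or lowest array far from the other 3, 24 checks in all, of which chance flags about 1 in 20. The measures share arrays, so the flags are not independent. 7 checks stood out, in 2 arrays.

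Wild-type replicate 2 had a median expression of 5.44, against 5.25 to 5.28 in the other wild-type arrays, and an interquartile range of 2.90, against 3.14 to 3.18. Its genes of the G1 list averaged −0.102 relative to all arrays, against 0.010 to 0.021 in the other wild-type arrays, and those of the S list −0.099, against 0.0046 to 0.020. Its G2M genes were low as well, at −0.12, though not flagged, so the low averages do not mark 1 phase. Whether the lists fell beyond the brightness trend of this array, given below, was not tested array by array. In cKO replicate 1 the interquartile range was 3.11, against 3.15 to 3.16 in the other cKO arrays, its S genes averaged −0.019, against 0.028 to 0.029, and its G2M genes −0.0041, against 0.037 to 0.045.

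Wild-type replicate 2 deviated from the mean of the other wild-type arrays by a root mean square of 0.276, and the other 7 arrays from theirs by 0.144 to 0.205. The median deviation from the other wild-type arrays was 0.160 in the dimmest tertile of genes, 0.156 in the middle and −0.063 in the brightest. A dependence on brightness is part of the pattern, but not all of it: after cyclic loess, which removes such dependence, its deviation was 0.234, above the highest of the other arrays, 0.195, by more than their SD of 0.020. A cKO pool labelled as wild type is excluded by its place at 0.096 on the axis from wild type to cKO, where the other wild-type arrays reached 0.118. RNA quality and a different mix of cells in that pool stay open and were not tested, since the genes were not named here, and no group of the design offers a biological explanation.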

How the results depend on the processing

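All alternatives for the cell cycle lists, cyclic loess and leaving out both arrays of lowest weight were chosen after seeing the data. The named genes were chosen as the largest rises and falls in these same arrays, and no other gene was followed through the alternatives. Their persistence is therefore no independent support. Over 17 alternatives each, ENSMUSG00000031073 ranged from 2.37 to 2.52, ENSMUSG00000062760 from 1.16 to 1.29 and ENSMUSG00000000560 from −2.18 to −1.89, all past the threshold. ENSMUSG00000054005 ranged from −1.58 to −1.36 and missed it only with the replicate block (limma adjusted p = 0.059). The count of genes at 2-fold or more stayed within 1.5 times of 18 except with the replicate block (11) and the lower limit of 0.58 (88). With the replicate number as a block, which takes up 3 degrees of freedom, 18 genes were called (6 higher, 12 lower), all among the 342. The labels do not say that the numbers pair the samples, and 1 of the 4 cKO arrays correlated best with its own number. The correlations cannot settle whether the samples were paired. Leaving out 1 array gave 119 to 303 calls, 56 to 151 higher and 61 to 152 lower, with fewer samples in each fit. Leaving out both arrays of lowest weight gave 106 (42 higher, 64 lower), 99 of them among the 342. Array weights, which gave wild-type replicate 2 a weight of 0.20, raised the count to 575 (303 higher, 272 lower), including 339 of the 342. The gene-by-gene test without shared variance gave 181 (79 higher, 102 lower). Centring on the median gave 196, with 65 lower. Without the dimmest 40% of genes 503 were called (288 higher, 215 lower), and at an adjusted p under 0.1, 505 (273 higher, 232 lower). Repeated quantile normalization, cyclic loess and the trend and robust prior gave 348, 344 and 449, sharing 296, 294 and 321 with the 342. Beyond the common shift that centring adds to every gene, the cause of these changes was not tested.

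The calls of the cell cycle lists depended on the setting, and all of them used the preset correlation of 0.01, below the estimated 0.22 to 0.25. Leaving out 1 array gave means of −0.0047 to 0.036 for G1, 0.0065 to 0.046 for S and 0.029 to 0.072 for G2M, the lowest each without wild-type replicate 2, where G1 changed sign. With means of 0.025, 0.034 and 0.058, an estimated correlation ended all 3 calls (adjusted p = 0.46 each). Fry, which tests each list against no change and not against other genes, gave adjusted p = 0.50, 0.49 and 0.44. Camera on ranks kept all 3 calls (adjusted p = 0.000443, 6.7e-05 and 9.0e-08), as did centring on the median, with means of 0.060, 0.068 and 0.093, shifted as all genes were (adjusted p = 0.0035, 0.000686 and 6.8e-06). Without the dimmest 40% of genes all 3 lists were also called, with weaker camera adjusted p = 0.042, 0.0073 and 7.0e-05 for G1, S and G2M. The G1 call also ended with repeated quantile normalization (0.021), and the G1 and S calls with array weights (0.0071 and 0.019), cyclic loess (0.019 and 0.024) and without both arrays of lowest weight (0.0065 and 0.018). The G2M list was still called under these 4 settings. The alternatives meant for Foxi3, its neighbours and the symbol-based lists were not run, and those on probe sets per gene and on rows tested could not differ from the main test. Without detection calls, dim genes could not be told from background, and 30 of the 342 genes lay below the 40th percentile of expression.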

Other observations

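All splits of the 8 arrays into 4 and 4 were fitted, a test chosen before the data were examined. Of the 35 splits, only 1, the genotypes, called as many as 342 genes, and the highest of the other 34 called 1. Each other split mixes the genotypes, so the genotype difference widens its groups and it is no pure measure of chance. The genotypes thus called the most genes of any split, but this cannot exclude chance or a difference that ran along with genotype. At an unadjusted p under 0.05 the genotypes gave 2531 genes by limma, against a median of 996.5 and a highest value of 1777 in the other splits. If no gene were changed, 1308 would be expected on average.

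The within-genotype SD was at least 0.5 on the log2 scale in 186 genes, a limit chosen after the values were seen. Their median expression was 3.80, against 5.29 over all genes. The most deviant array was wild-type replicate 2 in 49 of them and wild-type replicate 3 in 44. In wild-type replicate 2 the deviation was upward in 34 and downward in 15, and in wild-type replicate 3 upward in 15 and downward in 29.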
